A study of Homo sapiens with 12 samples.

How the data were processed

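Gene expression was measured in MCF7 cells, an established human breast cancer line, harvested 24 h after irradiation with electrons, per the labels. The sample titles say 9 or 23 IR doses, while the series design gives single doses of 9 Gy or 23 Gy, which are used here. Per the labels' protocols, 500 ng of total RNA (Trizol) was amplified by T7 transcription and labelled with Cy5 for irradiated cells and with Cy3 for untreated MCF7, with no dye swap. The labels gave 6 numbered biological replicates per dose. Scanner files were used for the 6 samples of 9 Gy, and the deposited value table for all 12. The scanner files of 23 Gy were not used here.

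Spot intensities were made by Agilent Feature Extraction 9.5.3.1 with protocol GE2-v5_95_Feb07 on array design 014850, per the file headers. Their log10 ratios of red over green are in the same scanner files, per the file headers. The other deposited values, those of the value table, have no unit given in the sources used here. Divided by 1e+09, its columns for 9 Gy matched the log10 ratio of the scanner file of the same sample in 45015 of 45015 spots within 1%, with Pearson's r of 0.999999. Scale and direction of the 9 Gy columns were taken from this match, and the 23 Gy columns were assumed to share them. The median of each of the 12 columns was 0. Between 7428 and 10248 values of a column were exactly 0, nearly all of spots with no signal above background in both channels on the 9 Gy scans, and these were taken as missing. Values were turned from log10 to log2.

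For the main analysis of 9 Gy, the mean intensity and the median local background of each spot were corrected by normexp with an offset of 50 and normalised by loess within each scan (limma 3.58.1, R 4.3.3). Control spots had weight 0 in loess and were left out after it, as were spots marked as outliers by Feature Extraction (113 to 144 per scan). The offset pulls the ratios of dim spots towards 0. Of the non-control spots, at most 1 per scan was saturated. Spots of a probe were averaged. A probe was kept if it was well above background in at least 1 channel on at least 3 of the 6 scans of 9 Gy, which 28249 probes were, and the same probes were used for 23 Gy. Of 41000 probes, 23845 were named through the accession in the file, 2018 through its symbol and 966 through an older symbol, using the RefSeq table of assembly GRCh38.p14 for names alone, and 14171 were not named. Each of 17528 genes was represented by its kept probe of highest mean intensity, and 13470 genes were tested at 9 Gy. Of 266 genes named by the rule below, 87 had several probes and 9 of these had probes of opposite sign beyond 0.2, namely BBC3, CNN2, ESR1, IFIT2, KRT18, MICB, NR4A3, ORC6 and PGK1. Probes of the same sign could also differ in size, as for ACTB (0.14 to 1.01 at 9 Gy). The size given for a gene is that of 1 probe unless said otherwise. Probe positions are those of the file, in hg17.

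The design fixed before the data were examined took the 6 samples of a dose as independent. The scanner headers of 9 Gy gave 3 scans of each of 2 arrays, and the same was inferred for 23 Gy from the spot deviations given in the results, so scans were averaged per array and n was 2 arrays. The fit over 6 samples is kept as an alternative. Nothing in the sources used here says whether the 2 arrays of a dose held RNA of separate cultures, so p-values measure only the spread between these arrays, which may be technical. The arrays correlated across genes with r of 0.983 at 9 Gy (0.952 in the deposited values) and 0.895 at 23 Gy. Their median SD per gene was 0.033 and 0.036.

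Each dose was compared with untreated cells by testing its mean log2 ratio against 0, and the doses with each other by the difference of their mean log2 ratios, with limma's lmFit and eBayes and Benjamini-Hochberg adjustment over genes, called at an adjusted p under 0.05 and also counted at 2-fold. The untreated RNA was hybridised on each array and counts as 1 control sample, so the ratio leaves out its own spread. The difference between doses cancels a dye bias shared by both, and cancels the reference only if the same untreated RNA was used. Residual degrees of freedom were 1 per dose and 2 between doses. The spread that limma pools over genes added 12.3 at 9 Gy, 1.85 at 23 Gy and 1.84 between doses. The calls at 9 Gy therefore rest largely on that pooled spread, and the others rest on it in part.

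Before the data were examined, 26 gene lists with 709 genes were written, of which 704 were on the array and 640 were tested: p53 targets, G2/M and mitosis, DNA replication and G1/S, replication-dependent histones, homologous recombination and Fanconi anaemia, break sensing and end joining, interferon-stimulated genes, NF-kB and secreted inflammatory factors, BCL2 family and death effectors, oestrogen response, luminal epithelial markers, basal and myoepithelial markers, mesenchymal genes, stem cell associated genes, NRF2 antioxidant genes, unfolded protein and ATF4 response, heat shock, immediate early and AP-1, cholesterol synthesis, glycolysis and hypoxia, lysosome and autophagy, antigen presentation and NK ligands, ribosome biogenesis and MYC targets, adhesion and cytoskeleton, fibroblast and other stromal cell markers, and leukocyte markers. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. None of the camera calls held with an estimated correlation, which 2 arrays determine poorly. By fry, which tests whether a list moves on balance one way and does not compare it with other genes, each list called by camera also passed. The rule for named genes was also fixed then. It took the 10 largest rises and falls of each comparison among called genes with the same sign on all samples and a probe above background in at least 1 channel on all 6 scans, up to 4 called members of each list with the largest changes, and CDKN1A, MDM2, GDF15, CCNB1, PLK1, MKI67, MCM2, ESR1, TFF1 and BCL2. Not all genes named by this rule are reported here. List members named because they moved against their list, namely TNFRSF10A, BBC3, EPCAM, CLDN7, TYMS and MYC, were chosen after their values were seen.

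The fit was tested on simulated data with 200 changed genes among 13473, and with the other members of the DNA replication list lowered by 0.5. For 9 Gy it called 79.1%, 94.0% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale and 1 of 13232 unchanged genes. For 23 Gy it called 49.3%, 77.6% and 90.9% and 6 unchanged genes, and between doses 61.2%, 83.6% and 100% and 10 of 13231 unchanged genes. The simulated noise was independent between arrays, with no dye bias, error of the untreated RNA or batch effect shared by them. False calls from such shared errors were therefore not tested. Far fewer genes changed in the simulation than were called in the data, so the Benjamini-Hochberg cut-off was stricter there. The shares called and the false calls therefore do not carry over to the real calls. Alternatives covered the background correction, the normalisation, the deposited values, the filter on dim probes, the probe rule, array weights, the array as a block, a replicate block, each replicate left out and the treatment of zeros. The precision of each value is limited by the number of arrays.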

Results

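The series measured messenger RNA in MCF7 cells, an established oestrogen receptor positive human breast cancer line, 24 h after 1 high dose of electrons of the kind delivered during surgery (intraoperative electron radiotherapy). There were 12 deposited samples, 6 taken as 9 Gy and 6 taken as 23 Gy. Each was a 2-colour scan of a whole-genome oligonucleotide array. Labelled RNA from irradiated cells carried Cy5 and RNA from untreated MCF7 cells carried Cy3 on each of the 12, so a positive log2 ratio means a higher level after irradiation. On the 6 scans of 9 Gy, between 61.0% and 68.6% of 43376 non-control spots were well above background in the irradiated channel, and between 63.5% and 67.6% in the untreated channel. The small number of arrays limits the precision of each value.

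The 6 samples of a dose were not treated as 6 hybridisations. Among 264 probes that were each spotted 10 times, the deviations of single spots from their probe's median correlated within replicates 1 to 3 and within replicates 4 to 6 of each dose, with Spearman's rho of at least 0.323. Between these sets and between doses rho was at most 0.168. For 9 Gy, scanner headers gave replicates 1 to 3 the same slide and array position, and replicates 4 to 6 another. Scans were therefore averaged per array, and all errors below are over n = 2 arrays per dose, of which the 23 Gy sets were inferred from the spot deviations alone.

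**Figure D1:**
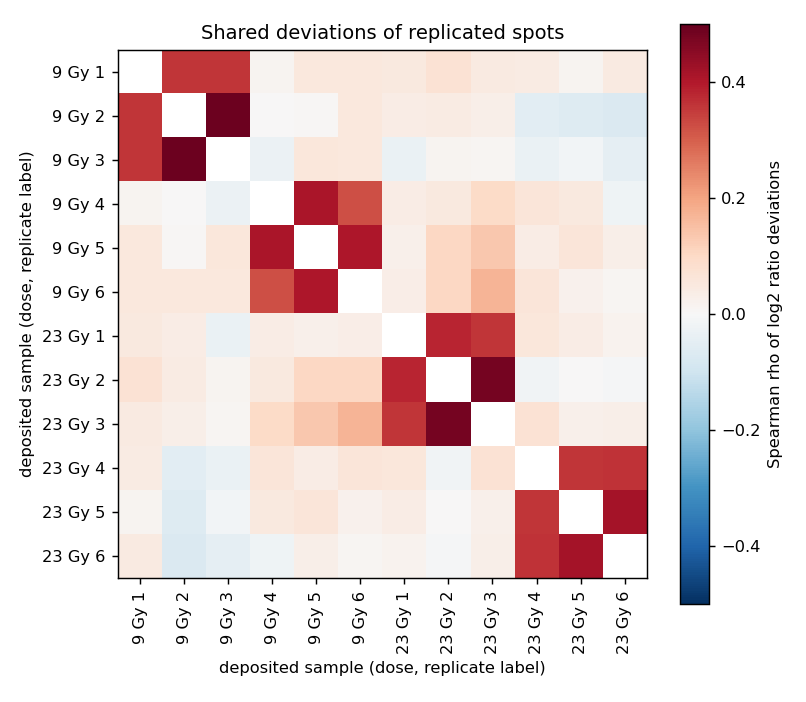
Spearman's rho of the log2 ratio deviations of replicated spots for each pair of the 12 deposited samples, which are on both axes in order of dose and replicate label, with colour giving rho. The 4 blocks of 3 samples along the diagonal hold rho of 0.323 or more, and the other pairs hold 0.168 or less.

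The first comparison asked which transcripts differed from untreated cells 24 h after 9 Gy. Immediate early genes, p53 target genes and interferon-stimulated genes were higher, and DNA replication and homologous recombination genes were lower. The largest rises included ATF3 (log2 change 2.78 ± 0.0012, SD, n = 2 arrays), a stress-induced transcription factor, and EGR2 (2.77 ± 0.067), EGR4 (2.67 ± 0.055), EGR3 (2.33 ± 0.035) and FOSB (2.24 ± 0.0027), transcription factors of the immediate early response. TNFRSF11B, the decoy receptor osteoprotegerin, rose by 2.39 ± 0.060, EDN2, a secreted endothelin, by 2.32 ± 0.049, ZFP36L2, an mRNA decay factor, by 2.22 ± 0.025 and ACTA2, smooth muscle actin, by 2.21 ± 0.20. NR4A3, an orphan nuclear receptor, gave 2.85 ± 0.029 with its brightest probe and -0.75 with another, so its direction depends on the probe. The largest falls were those of MAPK4 (-2.76 ± 0.0037), an atypical kinase, CEMIP (-2.71 ± 0.012), a hyaluronan-binding protein, ANKK1 (-2.47 ± 0.087), ZNF652 (-2.37 ± 0.17), AOX1 (-2.34 ± 0.045), aldehyde oxidase, TARP (-2.27 ± 0.017), DLST (-2.24 ± 0.037), HDAC10 (-2.23 ± 0.0076), a deacetylase, GPR157 (-2.19 ± 0.027) and MOAP1 (-2.19 ± 0.033). The adjusted p of these 20 genes was at most 1.1e-13 (limma, Benjamini-Hochberg). The other probe of HDAC10 gave -0.41. Those of ATF3 (1.33), TNFRSF11B (1.54), CEMIP (-1.71) and DLST (-1.56) also gave smaller changes of the same sign. In hg17 the probe of ATF3 lies at chromosome 1, 209182251 to 209182310, that of EGR2 at chromosome 10, 64241856 to 64241915, that of MAPK4 at chromosome 18, 46511989 to 46512052 and that of CEMIP at chromosome 15, 79030858 to 79030917.

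Of 13470 genes tested at 9 Gy, 218 were at least 2-fold higher and 184 at least 2-fold lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg). With no limit on size, 5731 were higher and 4819 lower. This balance depends on the scaling, since median centring in place of loess gave 8930 higher and 1818 lower, 1137 and 55 of them at least 2-fold. The deposited log ratios of the same arrays, to which no offset was added here, gave 786 genes at least 2-fold higher and 474 lower, and normexp without the offset gave 458 and 351.

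Among p53 targets, 42 of 44 tested members rose, 2 fell and 0 did not pass (42 and 2 adjusted over the list alone). The median was 0.79 (camera adjusted p = 4.9e-12, adjusted p = 0.558 with an estimated correlation). GDF15, a secreted stress cytokine, rose by 2.18 ± 0.15, TP53INP1 by 1.96 ± 0.051, FDXR by 1.85 ± 0.0033 and FAS, a death receptor, by 1.74 ± 0.026. The cell cycle inhibitor CDKN1A rose by 1.40 ± 0.026, MDM2, the ubiquitin ligase of p53, by 1.00 ± 0.028, and BAX, a pore-forming death effector, by 1.15 ± 0.0074. The lowest kept probes of CDKN1A, MDM2 and BAX gave 0.67, 0.32 and 0.45. The members that fell were TNFRSF10A (-0.075, and 0.091 with median centring in place of loess) and BBC3 (-0.26, and 0.77 with median centring). TNFRSF10A did not pass in several alternatives, among them the deposited log ratios (adjusted p = 0.301) and no filter on dim probes (adjusted p = 0.0547). The 3 probes of BBC3 ranged from -0.26 to 2.77, with a mean of 1.12. The probe of CDKN1A lies at chromosome 6, 36762684 to 36762743 and that of GDF15 at chromosome 19, 18360890 to 18360949 (hg17).

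In the immediate early and AP-1 list, 22 of 22 tested members rose, 0 fell and 0 did not pass (22 and 0 adjusted over the list alone). The median was 1.42 (camera adjusted p = 2.0e-11, adjusted p = 0.558 with an estimated correlation), and 16 members were at least 2-fold higher. Among interferon-stimulated genes, 32 of 35 tested members rose, 2 fell and 1 did not pass (32 and 2 adjusted over the list alone). The median was 0.44 (camera adjusted p = 1.6e-07, adjusted p = 0.558 with an estimated correlation), and 0.94 from the deposited log ratios. IFI27 rose by 1.79 ± 0.054, IFIT1, which binds viral RNA, by 1.74 ± 0.0049, IFITM1 by 1.23 ± 0.049 and IRF9, the DNA-binding part of the interferon-activated complex, by 1.20 ± 0.0096. Among NF-kB and secreted inflammatory genes, 16 of 24 tested members rose, 2 fell and 6 did not pass (16 and 2 adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.00205, adjusted p = 0.558 with an estimated correlation), and from the deposited log ratios the median was 0.66. Its members included PLAU, the urokinase protease, at 1.56 ± 0.022, RELB at 1.46 ± 0.093, NFKBIA, the inhibitor of NF-kB, at 1.26 ± 0.022 and LIF at 1.23 ± 0.11. From the deposited log ratios LIF was at 2.53. The other kept probe of LIF gave -0.037 with scanner values, so its rise depends on the probe. With median centring in place of loess the adjusted p of the NF-kB list was 0.0583. Among antigen presentation genes and NK cell ligands, 14 of 18 tested members rose, 4 fell and 0 did not pass (14 and 4 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.0138, adjusted p = 0.558 with an estimated correlation), with the peptide transporter TAP1 at 0.87 ± 0.019 and B2M, the light chain of HLA class I, at -0.67 ± 0.0064, which did not pass with median centring (-0.077, adjusted p = 0.126). The other probe of B2M gave -0.12.

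Among mesenchymal genes, 14 of 18 tested members rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone). The median was 0.34 (camera adjusted p = 9.3e-04, adjusted p = 0.558 with an estimated correlation), and 0.76 from the deposited log ratios. CCN2 rose by 2.00 ± 0.016 and CCN1 by 1.57 ± 0.080, both matricellular proteins, and the adjusted p of this list was 0.0583 with median centring. Among luminal epithelial markers, 14 of 18 tested members rose, 3 fell and 1 did not pass (14 and 3 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.0107, adjusted p = 0.558 with an estimated correlation), and from the deposited log ratios the adjusted p of this list was 0.0522. Keratins KRT19 (1.31 ± 0.39) and KRT8 (0.95 ± 0.11) rose, while EPCAM (-0.81) and CLDN7 (-0.82), surface adhesion proteins, fell, though EPCAM was at 0.00073 with median centring.

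In the DNA replication and G1/S list, 1 of 42 tested members rose, 41 fell and 0 did not pass (1 and 41 adjusted over the list alone). The median was -0.82 (camera adjusted p = 7.0e-15, adjusted p = 0.558 with an estimated correlation), and -0.33 with median centring, where it was still called (adjusted p = 4.1e-16). RRM2, a subunit of ribonucleotide reductase, fell with a log2 change of -1.75 ± 0.033, CDC45, part of the replicative helicase, with -1.68 ± 0.065, MCM6 with -1.39 ± 0.11 and MCM2 with -1.05 ± 0.011. The member that rose was TYMS (0.18), thymidylate synthase. Among homologous recombination and Fanconi anaemia genes, 2 of 26 tested members rose, 23 fell and 1 did not pass (2 and 23 adjusted over the list alone). The median was -0.60 (camera adjusted p = 6.0e-08, adjusted p = 0.558 with an estimated correlation), and -0.22 with median centring, where it was still called (adjusted p = 2.6e-09). POLQ, the polymerase of theta-mediated end joining, fell with -1.84 ± 0.043, FANCA with -1.11 ± 0.018, BRCA1 with -1.05 ± 0.016 and the exonuclease gene EXO1 with -1.02 ± 0.039. The other probe of POLQ gave -0.57. Among break sensing and end joining genes, 2 of 22 tested members rose, 14 fell and 6 did not pass (2 and 14 adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.0126, adjusted p = 0.558 with an estimated correlation), with the checkpoint kinase CHEK1 at -0.89 ± 0.018, and this call ended with median centring (list median 0.19, adjusted p = 0.167) and without replicate 2 (0.065) or 6 (0.06).

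Under that median centring the median of all tested genes was 0.28 instead of 0.030, and 83.1% instead of 54.3% of the called genes were higher. Among cholesterol synthesis genes, 4 of 23 tested members rose, 16 fell and 3 did not pass (4 and 16 adjusted over the list alone). The median was -0.40 (camera adjusted p = 9.3e-04, adjusted p = 0.558 with an estimated correlation), and the call ended under median centring (list median 0.12, adjusted p = 0.146). MSMO1 fell with -1.38 ± 0.014 and IDI1 with -1.11 ± 0.032, while the other probe of MSMO1 gave -0.22. Among ribosome biogenesis and MYC target genes, 6 of 27 tested members rose, 19 fell and 2 did not pass (6 and 19 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.00727, adjusted p = 0.558 with an estimated correlation), and the call ended under median centring, where the median turned to 0.31 (adjusted p = 0.849). ODC1, the first enzyme of polyamine synthesis, had -0.89 ± 0.014.

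The G2/M and mitosis list was not called at 9 Gy, where 14 of 44 tested members rose, 23 fell and 7 did not pass (14 and 23 adjusted over the list alone) (list median -0.11, camera adjusted p = 0.141). MAD2L1, a spindle checkpoint gene, fell with -1.34 ± 0.078 and CDK1 with -0.87 ± 0.017, while the ubiquitin-conjugating enzyme gene UBE2C rose by 0.75 ± 0.027. CCNB1 had -0.24 ± 0.0076 and MKI67 -0.18 ± 0.089, with 0.44 and 0.056 under median centring, and PLK1 had -0.0036 ± 0.048 (adjusted p = 0.924, limma), with 0.64 under median centring. Replication-dependent histones were not called either, where 20 of 43 tested members rose, 11 fell and 12 did not pass (20 and 11 adjusted over the list alone) (list median 0.066, camera adjusted p = 0.562), but were called higher under median centring (list median 0.56, adjusted p = 0.00504). The oestrogen receptor gene ESR1 had -0.17 ± 0.0017 and its target TFF1 -0.41 ± 0.10, with 0.30 and 0.77 under median centring, and BCL2, an inhibitor of cell death, rose by 0.53 ± 0.15. The other probe of BCL2 gave 0.10. The p-values measure only the spread between 2 arrays, which may be technical, and the ratio leaves out the spread of the untreated control. A gene-specific dye bias stays in these ratios.

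The second comparison asked the same question for 23 Gy, from the deposited log ratios. The 9 Gy values above were processed in another way, so sizes at the doses are set side by side only from the deposited values. At 23 Gy p53 targets were higher, and DNA replication, G2/M and replication-dependent histone genes were lower, than in untreated cells. FAS rose by 3.09 ± 0.031 (SD, n = 2 arrays), ACTA2 by 2.51 ± 0.00078 and GDF15 by 2.38 ± 0.032. Another 6 of the 10 largest rises, those of APOC2, APOBEC3H, TRIM49, OR2W3, ADAMTS15 and ZNF518B, were of probes not well above background in the untreated channel on at least 5 of the 6 scans of 9 Gy, and no fold is given for them. The largest falls with both channels above background there were of the linker histone gene H1-5 (-2.88 ± 0.052), the core histone genes H4C3 (-2.63 ± 0.13), H4C13 (-2.58 ± 0.020), H4C2 (-2.50 ± 0.011) and H4C4 (-2.32 ± 0.0016), and ACTL8 (-2.11 ± 0.071), LINC00052 (-1.83 ± 0.074) and WDR76 (-1.80 ± 0.035). MIXL1 and ACSBG1 were also among the 10 largest falls, with the irradiated channel above background on 1 and 3 of the 6 scans of 9 Gy. The adjusted p of the genes given with a value was 0.0052 (limma, Benjamini-Hochberg). The other probe of LINC00052 gave -0.60. In hg17 the probe of FAS lies at chromosome 10, 90764525 to 90764584, that of H1-5 at chromosome 6, 27942608 to 27942667 and that of H4C2 at chromosome 6, 26135128 to 26135187.

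Of 13396 genes tested at 23 Gy, 151 were at least 2-fold higher and 106 at least 2-fold lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 3986 were higher and 4235 lower with no limit on size. Among genes well above background in both channels on all scans of 9 Gy, 79 were at least 2-fold higher and 76 lower. With no filter on dim probes, and more genes tested, 194 were at least 2-fold higher and 167 lower.

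Among p53 targets, 41 of 44 tested members rose, 1 fell and 2 did not pass (41 and 1 adjusted over the list alone). The median was 0.91 (camera adjusted p = 7.5e-14, adjusted p = 0.462 with an estimated correlation). SPATA18 rose by 2.13 ± 0.0078, the decoy receptor gene TNFRSF10C by 1.70 ± 0.054, CDKN1A by 1.38 ± 0.0034 and MDM2 by 1.32 ± 0.016. BBC3 had -0.50 ± 0.22, and its 3 probes ranged from -0.50 to 1.66. In the immediate early and AP-1 list, 18 of 22 tested members rose, 1 fell and 3 did not pass (18 and 1 adjusted over the list alone). The median was 0.60 (camera adjusted p = 2.2e-05, adjusted p = 0.462 with an estimated correlation). ATF3 rose by 1.58 ± 0.028, EGR2 by 1.28 ± 0.0063 and FOSL1 by 1.23 ± 0.16, while MYC fell (-0.41). Among NF-kB and secreted inflammatory genes, 13 of 23 tested members rose, 4 fell and 6 did not pass (13 and 4 adjusted over the list alone). The median was 0.35 (camera adjusted p = 0.00949, adjusted p = 0.462 with an estimated correlation), with LIF at 1.98 ± 0.16 and INHBA at 0.98 ± 0.031. The other kept probe of LIF had no value over both arrays of 23 Gy. Among interferon-stimulated genes, 20 of 35 tested members rose, 4 fell and 11 did not pass (20 and 4 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.00334, adjusted p = 0.462 with an estimated correlation), with IRF9 at 0.73 ± 0.056 and TAP1 at 0.58 ± 0.038. Among antigen presentation genes and NK cell ligands, 12 of 18 tested members rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.0204, adjusted p = 0.462 with an estimated correlation), with TAPBP at 0.45 ± 0.042 and ULBP2, a ligand of the NK receptor NKG2D, at 0.41 ± 0.020.

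In the DNA replication and G1/S list, 1 of 42 tested members rose, 40 fell and 1 did not pass (1 and 40 adjusted over the list alone). The median was -0.94 (camera adjusted p = 7.5e-14, adjusted p = 0.462 with an estimated correlation). MCM7 fell with -1.49 ± 0.018, CDC45 with -1.41 ± 0.045, MCM6 with -1.40 ± 0.034 and MCM2 with -1.38 ± 0.042. Among G2/M and mitosis genes, 0 of 44 tested members rose, 42 fell and 2 did not pass (0 and 42 adjusted over the list alone). The median was -0.48 (camera adjusted p = 7.2e-12, adjusted p = 0.462 with an estimated correlation). The motor genes KIF11 and KIF14 fell with -0.99 ± 0.082 and -0.97 ± 0.088, the proliferation marker MKI67 with -0.81 ± 0.065, CCNA2 with -0.79 ± 0.0036, PLK1 with -0.76 ± 0.0070 and CCNB1 with -0.43 ± 0.12. Among replication-dependent histones, 1 of 43 tested members rose, 34 fell and 8 did not pass (1 and 38 adjusted over the list alone). The median was -0.32 (camera adjusted p = 4.7e-09, adjusted p = 0.462 with an estimated correlation), and 8 were at least 2-fold lower. Histone genes of 1 type are close in sequence, so a probe may also bind the RNA of other copies. Among homologous recombination and Fanconi anaemia genes, 0 of 26 tested members rose, 24 fell and 2 did not pass (0 and 25 adjusted over the list alone). The median was -0.56 (camera adjusted p = 1.2e-08, adjusted p = 0.462 with an estimated correlation), with EXO1 at -1.17 ± 0.025, XRCC2 at -1.12 ± 0.18 and RAD54L at -1.03 ± 0.00078. The other probe of XRCC2 gave -0.53. Among break sensing and end joining genes, 1 of 21 tested members rose, 18 fell and 2 did not pass (1 and 18 adjusted over the list alone). The median was -0.30 (camera adjusted p = 1.4e-04, adjusted p = 0.462 with an estimated correlation), with CHEK1 at -1.15 ± 0.022 and the histone variant gene H2AX at -0.78 ± 0.038. Among ribosome biogenesis and MYC target genes, 1 of 27 tested members rose, 23 fell and 3 did not pass (1 and 23 adjusted over the list alone). The median was -0.36 (camera adjusted p = 4.0e-06, adjusted p = 0.462 with an estimated correlation), with the nucleolar genes NOP56 at -0.71 ± 0.021 and NCL at -0.53 ± 0.020.

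ESR1 passed narrowly with 0.10 ± 0.020 (adjusted p = 0.04996, limma), and not with median centring (adjusted p = 0.0539). The 3 probes of ESR1 ranged from -0.33 to 0.37 at 23 Gy, so its direction depends on the probe. TFF1 had 0.65 ± 0.47 (adjusted p = 0.0745), which passed only in alternatives such as genes well above background in both channels (adjusted p = 0.0258), while BCL2 rose by 0.23 ± 0.11. Markers of other cell types were measured as well. Among fibroblast and other stromal markers, 5 of 8 tested members rose, 1 fell and 2 did not pass (5 and 1 adjusted over the list alone). The median was 0.31 (camera adjusted p = 0.022, adjusted p = 0.462 with an estimated correlation), with PDGFRA at 0.72 ± 0.020 and the collagen gene COL5A1 at 0.37 ± 0.066. Leukocyte markers were not called at 23 Gy, where 6 of 10 tested members rose, 0 fell and 4 did not pass (6 and 0 adjusted over the list alone) (list median 0.16, camera adjusted p = 0.20). With only genes well above background in both channels, the adjusted p of the stromal list was 0.0663. Which probes were above background was known from the scans of 9 Gy only.

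**Figure D2:**
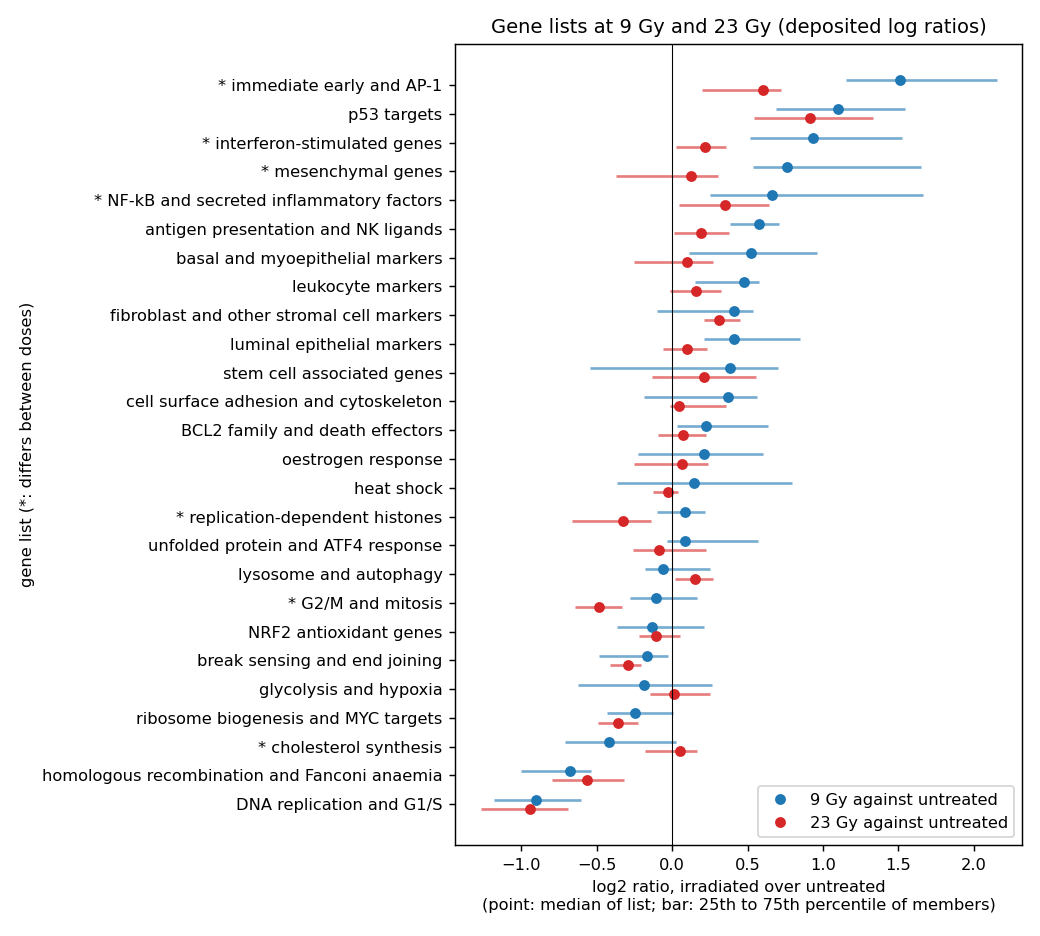
Median log2 ratio of irradiated over untreated (points) and the range from the 25th to the 75th percentile of members (bars) for the 26 gene lists at 9 Gy (blue) and 23 Gy (red), all from the deposited log ratios of 2 arrays per dose, with asterisks on lists that differed between doses (camera with a preset correlation). The p53 targets have medians of 1.10 at 9 Gy and 0.91 at 23 Gy, and the immediate early list 1.51 and 0.60.

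The third comparison asked which transcripts differed between the doses. It used the deposited log ratios of both doses, and values are 23 Gy minus 9 Gy with the standard error of the fit (n = 2 arrays per dose). Immediate early, interferon-stimulated, mesenchymal, histone and G2/M genes were lower at 23 Gy than at 9 Gy, and cholesterol synthesis genes were higher. CEMIP differed by 4.06 ± 0.046, from -3.08 at 9 Gy to 0.98 at 23 Gy, and MAPK4 by 3.69 ± 0.037, from -3.04 to 0.65. SMOC1, a secreted calcium-binding protein, differed by 3.47 ± 0.054 and CACNB2, a calcium channel subunit, by 3.29 ± 0.082. The 2 kept probes of SMOC1 ranged from -2.02 to -0.025 at 9 Gy with scanner values. At 23 Gy they ranged from 0.89 to 1.52, so the size of its difference depends on the probe. LRRC2 was lower by -3.46 ± 0.033 and SYNDIG1, a synaptic protein, by -2.95 ± 0.15 on the log2 scale. The adjusted p of these 6 genes was at most 5.4e-04 (limma, Benjamini-Hochberg). The other 14 of the 20 largest differences were of genes with a channel not well above background on 3 or more scans of 9 Gy. They were FGG, MICOS10P1, TCN1, SYNPO2, DSCR8 and MBTD1, which were higher at 23 Gy, and SPANXA1, S100A9, ARHGAP36, TNF, RAMP3, CDSN, S100A8 and ANXA1, which were lower. The probe of SMOC1 lies at chromosome 14, 69568535 to 69568594 and that of LRRC2 at chromosome 3, 46532390 to 46532463 (hg17).

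Of 13380 genes tested, 506 were at least 2-fold higher and 635 at least 2-fold lower at 23 Gy than at 9 Gy at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 3870 were higher and 5769 lower with no limit on size. The median gene differed by -0.11. The SD of the log2 ratios over genes was 0.63 at 9 Gy and 0.37 at 23 Gy.

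In the immediate early and AP-1 list, 0 of 22 tested members were higher at 23 Gy, 21 were lower and 1 did not pass (0 and 21 adjusted over the list alone). The median was -1.10 (camera adjusted p = 4.6e-06, adjusted p = 0.252 with an estimated correlation). EGR3 differed by -1.98 ± 0.058, EGR2 by -1.83 ± 0.033, ZFP36 by -1.58 ± 0.032 and JUNB by -1.47 ± 0.033. Among interferon-stimulated genes, 3 of 35 tested members were higher at 23 Gy, 31 were lower and 1 did not pass (3 and 31 adjusted over the list alone). The median was -0.68 (camera adjusted p = 1.1e-04, adjusted p = 0.252 with an estimated correlation), with IFIT1 at -1.81 ± 0.033. Among NF-kB and secreted inflammatory genes, 3 of 23 tested members were higher at 23 Gy, 17 were lower and 3 did not pass (3 and 17 adjusted over the list alone). The median was -0.55 (camera adjusted p = 0.0376, adjusted p = 0.408 with an estimated correlation), with RELB at -1.45 ± 0.064. That call ended with quantile normalization (adjusted p = 0.217) and with genes well above background in both channels (adjusted p = 0.163). Among mesenchymal genes, 0 of 18 tested members were higher at 23 Gy, 14 were lower and 4 did not pass (0 and 14 adjusted over the list alone). The median was -1.14 (camera adjusted p = 0.00734, adjusted p = 0.40 with an estimated correlation), with CCN2 at -2.19 ± 0.033, from 2.38 at 9 Gy to 0.19 at 23 Gy.

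Among replication-dependent histones, 0 of 43 tested members were higher at 23 Gy, 35 were lower and 8 did not pass (0 and 37 adjusted over the list alone). The median was -0.52 (camera adjusted p = 6.7e-06, adjusted p = 0.252 with an estimated correlation). H4C5 differed by -2.38 ± 0.049, H4C2 by -2.22 ± 0.032 and H1-5 by -2.06 ± 0.054. After a trend with GC content was removed from each array, the median of the histones was -0.30 (adjusted p = 0.00503), with 3 members higher and 26 lower. Among G2/M and mitosis genes, 3 of 44 tested members were higher at 23 Gy, 35 were lower and 6 did not pass (4 and 37 adjusted over the list alone). The median was -0.45 (camera adjusted p = 2.5e-04, adjusted p = 0.252 with an estimated correlation). The kinesin gene KIF20A differed by -1.25 ± 0.032, UBE2C by -1.07 ± 0.040, PLK1 by -0.80 ± 0.034, MKI67 by -0.59 ± 0.071 and CCNB1 by -0.26 ± 0.068. Among cholesterol synthesis genes, 14 of 23 tested members were higher at 23 Gy, 3 were lower and 6 did not pass (14 and 3 adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.00418, adjusted p = 0.408 with an estimated correlation). MSMO1 differed by 2.57 ± 0.053, from -2.41 at 9 Gy to 0.15 at 23 Gy, and IDI1 by 1.34 ± 0.043. The 2 kept probes of MSMO1 were at -1.38 and -0.22 at 9 Gy with scanner values, so its size depends on the probe.

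The p53 targets were not called between doses, where 12 of 44 tested members were higher at 23 Gy, 19 were lower and 13 did not pass (12 and 19 adjusted over the list alone) (list median -0.068, camera adjusted p = 0.864), and with quantile normalization the median turned to 0.23 (adjusted p = 0.00296). With the 23 Gy ratios stretched to the SD of 9 Gy over genes, the p53 median was 0.51 (adjusted p = 4.8e-06), with 29 members higher and 5 lower. CDKN1A had -0.064 ± 0.035 (adjusted p = 0.173, limma) and MDM2 -0.071 ± 0.041 (adjusted p = 0.193), which turned to 0.39 and 0.37 with quantile normalization. GDF15 was higher by 0.32 ± 0.085 (adjusted p = 0.0322), while PLK2 (-1.40 ± 0.038) and BAX (-1.05 ± 0.034), both listed p53 targets, were lower. The DNA replication and G1/S list was not called (list median -0.041, camera adjusted p = 0.893) and had a median of -0.62 with quantile normalization, which made it a call. MCM2 differed by -0.30 ± 0.038, ESR1 by 0.26 ± 0.033, TFF1 by 1.27 ± 0.24 and BCL2 by -0.42 ± 0.080. Each dose lay on hybridisations of its own, so dose and hybridisation batch cannot be told apart.

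**Figure D3:**
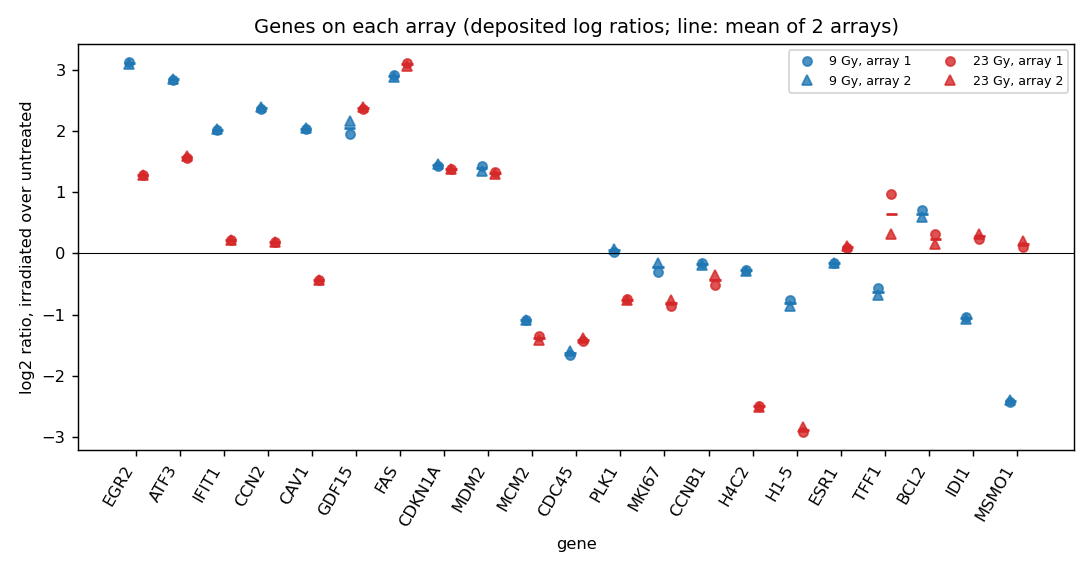
Log2 ratio of irradiated over untreated (vertical axis) for 21 genes (horizontal axis) on each of 2 arrays of 9 Gy (blue) and of 23 Gy (red), from the deposited log ratios, with a line at the mean of the 2 arrays. EGR2 lies at 3.11 at 9 Gy and 1.28 at 23 Gy, CDKN1A at 1.45 and 1.38, and H4C2 at -0.28 and -2.50.

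Across 13380 genes, the log2 changes at the doses correlated with Pearson's r of 0.331 and Spearman's rho of 0.280, and genes are not independent replicates. Deviations between the 2 arrays of each dose correlated across doses with r = 0.0020. Such deviations cancel what both arrays share, a common control or dye bias included. If both doses were compared with the same untreated RNA, unchanged groups would also correlate. Over 100 simulations of such groups r averaged 0.663. That value was fixed by giving the untreated RNA and each array the same spread, so it cannot be set against the observed 0.331. The simulated covariance averaged 0.0165, against an observed covariance of 0.0772. In these simulations the untreated RNA had the spread seen between the arrays of a dose, which may be technical. A larger spread would raise the simulated covariance. A gene-specific dye bias shared by both doses would also add covariance, and the simulations held none. These values therefore cannot tell how much of the observed covariance comes from a shared untreated RNA or from the dyes. Of 785 genes at least 2-fold higher at 9 Gy and 151 at 23 Gy, both from the deposited values, 101 were shared, where independent lists would share 8.86. Of 474 and 105 genes at least 2-fold lower, 37 were shared, where independent lists would share 3.72. With no limit on size, 2223 higher and 1973 lower genes were shared, where independent lists would share 1761 and 1393, while 1219 genes higher and 1026 lower at 9 Gy went the other way at 23 Gy. Scanner calls at 9 Gy gave fewer shared genes at 2-fold, 29 higher and 10 lower, where independent lists would share 2.46 and 1.46. Part of the excess may come from the shared control or from a dye bias shared by both doses. Neither was simulated for these overlaps.

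**Figure D4:**
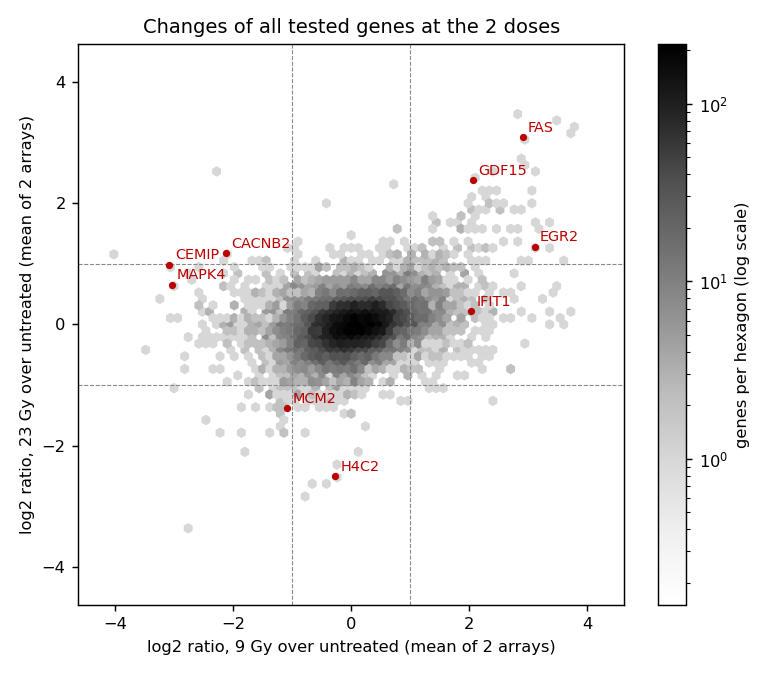
Mean log2 ratio over 2 arrays at 9 Gy (horizontal axis) and at 23 Gy (vertical axis) for 13380 genes, shaded by genes per hexagon on a log scale, with dashed lines at 2-fold and 9 genes named. FAS lies at 2.90 and 3.09, IFIT1 at 2.02 and 0.22, H4C2 at -0.28 and -2.50, and CEMIP at -3.08 and 0.98.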

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

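The tests of list differences between doses were planned, while all tests of rescans, of unnamed probes, of the range of ratios, of dye bias and of splits were chosen after the results were seen. What the test of GC content on the lists should show was written before its result. With 2 arrays per dose, no test for a sample far from its group was possible.

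The lists that differed between doses had medians of 23 Gy minus 9 Gy of -1.10 (immediate early and AP-1, from 1.51 at 9 Gy to 0.60 at 23 Gy), -0.68 (interferon-stimulated, from 0.94 to 0.22), -0.55 (NF-kB, from 0.66 to 0.35), -1.14 (mesenchymal, from 0.76 to 0.13), -0.52 (replication-dependent histones, from 0.084 to -0.32), -0.45 (G2/M and mitosis, from -0.10 to -0.48) and 0.39 (cholesterol synthesis, from -0.42 to 0.055). The camera adjusted p was at most 0.0376, and between 0.252 and 0.408 with an estimated correlation.

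The immediate early, interferon and NF-kB lists were lower at the higher dose. GC content of the probes was set against this because log2 ratios correlated with it across probes by Spearman's rho of 0.153 at 9 Gy and -0.161 at 23 Gy, but after this trend was removed from each array the median nearest 0 was still -0.366 (camera adjusted p at most 0.0272). The ratios had a smaller SD at 23 Gy, with a ratio of the doses of 2.02 over probes, unnamed ones included, and 1.70 over genes. After the 23 Gy ratios were stretched by the ratio over probes, the immediate early and interferon medians were still at or below -0.524 (adjusted p at most 0.0254), whereas for the NF-kB list the median was -0.405 with an adjusted p of 0.797. With the ratio over genes, the immediate early and interferon medians were at or below -0.569 (adjusted p at most 0.00275), and the NF-kB median was -0.531 (adjusted p = 0.423), so this explanation stays open for the NF-kB list. What stays open for all 3 lists is a difference in hybridisation, untreated RNA or handling between the doses, which cannot be told apart from dose because each dose lay on arrays of its own, and a biological effect of dose, which was not separated from them.

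Samples with replicate numbers 1 to 3, and 4 to 6, of each dose deviated together. The rho of their spot deviations was at least 0.323 within a set and at most 0.168 elsewhere. Separate arrays of a slide or day would not share damaged spots, but replicates 1 to 3 of 9 Gy shared 84.6% of spots marked as non-uniform, against 5.56% between sets. These shares are of the scan with fewer marked spots in each pair, summed over pairs (55 of 65 and 3 of 54, with a spot counted in each pair). Replicate 3 had more marked spots than the others (35), of which 20 were shared with replicate 1. Replicates 4 to 6 shared 54.5% on the same basis, but only 6 of 11 and 1 of 3 in some pairs, which is too few to decide. Within each set of 9 Gy the scanner headers gave the same slide and array position. For 23 Gy the repeated scan was inferred from the deviations that define the pattern and was not tested by other values, so separate arrays stay open there. No biological explanation was tested, since the labels name none.

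Among probes without a RefSeq name, which entered no comparison, 15.7% fell at least 2-fold at 9 Gy in the deposited values, against 4.66% of named probes. With scanner values, the main analysis of 9 Gy, these shares were 3.79% and 1.29%. At 23 Gy these shares were 0.580% and 0.722%. Dim signal alone would bring the ratio of the shares near 1 among probes well above background in both channels, where it was 2.90. GC content would do so within 5 bins of GC content, where the ratio ran from 2.04 to 3.85. A dye bias alike at both doses would raise the share at 23 Gy too, where the ratio was 0.804. Named and unnamed probes were not matched in brightness, so a part played by dim signal stays open. An effect of 9 Gy on unannotated or intronic transcripts also stays open. So does a difference between doses in RNA preparation, labelling or hybridisation, such as a dye bias at 9 Gy alone. Neither of these was tested.

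In 12 genes the change was at least 2-fold in opposite directions at the doses, from the deposited values. With scanner values at 9 Gy this held for 1 gene that was higher and 2 that were lower there. Of the 12, CACNB2 (-2.12 at 9 Gy and 1.17 at 23 Gy), ADAMTS9 (-1.67 and 1.02), GARIN1B (-1.49 and 1.03), HOPX (-1.46 and 1.02), BDKRB1 (-1.09 and 1.30), TCF7L1 (1.28 and -1.07) and H4C5 (1.38 and -1.002) were well above background in both channels on all scans of 9 Gy. Those other than CACNB2 and H4C5 were named after their values were seen. Of the 3 splits of the 4 arrays into pairs, the real one gave 1 of 3 results as large, with 1141 genes at least 2-fold apart, and the highest other split gave 0 (limma). At an unadjusted p under 0.05 the other splits gave 30 and 28 genes and the real one 10009. Each other split put 1 array of each dose on each side, so the difference between doses entered its error and few calls were fixed in advance. The other splits therefore do not show what unrelated arrays would give, and there are too few splits for a share under 0.05.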

How the results depend on the processing

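The fits over 6 scans, 6 columns or 12 columns as independent follow the design fixed before the data were examined, and became alternatives after that. Among the others, normexp without an offset, those that leave out a whole array, zeros kept as ratios of 1, the fits of 9 Gy with both doses, and the correlations of strongly changed genes, of scanner values and of genes bright in both channels were chosen after seeing the data. The cause of a change was not tested except where the construction of the alternative shows it. Signal over background limited the filter, since it was known for 9 Gy only.

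At 9 Gy, Agilent processed signals gave 786 genes at least 2-fold higher and 476 lower, the deposited values 786 and 474, and those values with both doses in the same fit 786 and 473, against 218 and 184. Normexp without an offset, which changed the offset alone, gave 458 and 351, so the offset alone did not give the whole difference. Median centring gave 8930 genes higher and 1818 lower, 1137 and 55 of them at least 2-fold, and 2 lists lower. It turned the median of the ribosome biogenesis list to 0.31, and CCNB1 to 0.44, PLK1 to 0.64, MKI67 to 0.056, ESR1 to 0.30, TFF1 to 0.77, TNFRSF10A to 0.091, BBC3 to 0.77 and EPCAM to 0.00073. BBC3 also turned, to 1.12, with the mean of its probes. Leaving out each replicate, or an array, gave 218 to 801 genes at least 2-fold higher and 184 to 504 lower, where the highest values come from the deposited values. Taking the 6 scans as independent gave 6292 genes higher and 5218 lower, and taking the array as a random block 6016 and 5034.

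At 23 Gy, no filter on dim probes gave 167 genes at least 2-fold lower against 106, with more genes tested, and genes well above background in both channels gave 79 at least 2-fold higher against 151, with fewer genes tested. Leaving out each replicate, or an array, gave 2577 to 3980 genes higher and 2728 to 4240 lower, lowest without replicates 1 to 3, which leaves 1 array assumed to vary like the others. BBC3 turned to 0.69 with the mean of its probes. The 6 columns as independent gave 5255 and 5436, and ended the call of the stromal list (adjusted p = 0.0548).

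Between doses, quantile normalization gave 3 lists higher against 1, and turned the p53 list to 0.23, the replication list to -0.62, CDKN1A to 0.39 and MDM2 to 0.37. The 12 columns as independent gave 4586 genes higher and 6665 lower, and ended the call of the NF-kB list (adjusted p = 0.101). Correlations of the doses were 0.410 in genes at least 2-fold changed, 0.268 with scanner values and 0.293 in genes bright in both channels, against 0.331. With scanner calls at 9 Gy, 29 genes at least 2-fold higher and 10 lower were shared.

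With an estimated correlation (camera), 0 lists were higher and 0 lower in each comparison, and at an unadjusted p under 0.05 the counts were 0 at 9 Gy, 0 at 23 Gy and 4 between doses. By fry, 14 lists were higher and 9 lower at 9 Gy, 14 higher at 23 Gy, and 5 higher and 17 lower between doses. By fry the unfolded protein list at 23 Gy (adjusted p = 0.0297) and the replication list between doses (0.035) had the direction opposite to that of camera.

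The replicate numbers did not pair the samples across doses, since deviations of the arrays correlated with r = 0.0020. A replicate block gave 3680 genes higher and 5583 lower, 506 and 637 of them at least 2-fold, and over 12 columns 4574 and 6643, with the NF-kB list no longer called (0.10). Array weights gave 3869 and 5750 between doses, and were not run within a dose, where 2 arrays get equal weights. The other alternatives kept each count within 1.5 times.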

Other observations

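The lists below were not called at 9 Gy in the main analysis. Among BCL2 family and death effector genes, 15 of 26 tested members rose, 5 fell and 6 did not pass (15 and 5 adjusted over the list alone) at 9 Gy (list median 0.14, camera adjusted p = 0.114). BMF, which promotes cell death, had 1.51 ± 0.10 at 9 Gy and -0.63 ± 0.027 at 23 Gy, a difference of -2.13 ± 0.060, all from the deposited values, while CYCS, cytochrome c, fell with -0.82 ± 0.023 at 9 Gy. Among oestrogen response genes, 17 of 30 tested members rose, 12 fell and 1 did not pass (17 and 12 adjusted over the list alone) at 9 Gy (list median 0.19, camera adjusted p = 0.403). IGFBP5 rose by 2.07 ± 0.020 and the retinoic acid receptor gene RARA by 1.49 ± 0.0023, while AGR2, a protein disulphide isomerase, fell with -1.03 ± 0.090. The other probe of RARA gave 0.17, and the 3 kept probes of IGFBP5 ranged from 0.79 to 2.07. Among basal and myoepithelial markers, 9 of 13 tested members rose, 2 fell and 2 did not pass (9 and 2 adjusted over the list alone) at 9 Gy (list median 0.26, camera adjusted p = 0.0619). This list was called with no filter on dim probes (adjusted p = 0.0319), with the mean of all probes (0.0466) and without replicate 2, 4 or 6 (at most 0.0425). CAV1, the coat protein of caveolae, had 2.04 ± 0.0044 at 9 Gy and -0.44 ± 0.0078 at 23 Gy, and the laminin gene LAMA3 -1.55 ± 0.39 and 0.99 ± 0.069, all from the deposited values. Among stem cell associated genes, 12 of 20 tested members rose, 7 fell and 1 did not pass (12 and 7 adjusted over the list alone) at 9 Gy (list median 0.14, camera adjusted p = 0.556). HES1 rose by 1.14 ± 0.055, and the efflux pump gene ABCG2 fell with -1.11 ± 0.041 at 9 Gy, while SOX9 rose by 1.06 ± 0.062 and SOX2 fell with -1.03 ± 0.051 at 23 Gy.

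Lysosome and autophagy genes were higher at 23 Gy, where 14 of 25 tested members rose, 3 fell and 8 did not pass (15 and 3 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.0182, adjusted p = 0.462 with an estimated correlation). WIPI1 rose by 0.57 ± 0.014, the protease gene CTSL by 0.47 ± 0.012 and MAP1LC3B, the autophagosome marker LC3B, by 0.36 ± 0.019. At 9 Gy this list was not called, where 9 of 25 tested members rose, 12 fell and 4 did not pass (9 and 12 adjusted over the list alone) (list median -0.048, camera adjusted p = 0.562), and between doses its adjusted p was 0.0948. Among NRF2 antioxidant genes, 9 of 27 tested members rose, 15 fell and 3 did not pass (9 and 15 adjusted over the list alone) at 9 Gy (list median -0.12, camera adjusted p = 0.20), with HMOX1, haem oxygenase, at 0.99 ± 0.0013. Among unfolded protein and ATF4 response genes, 13 of 24 tested members rose, 6 fell and 5 did not pass (13 and 6 adjusted over the list alone) at 9 Gy (list median 0.10, camera adjusted p = 0.316), with PPP1R15A, a phosphatase subunit, at 1.73 ± 0.011 and asparagine synthetase (ASNS) at -0.87 ± 0.032. The other probe of ASNS gave -0.044 at 9 Gy, so its fall depends on the probe. At 23 Gy PHGDH, the first enzyme of serine synthesis, fell with -1.16 ± 0.059. Among heat shock genes, 8 of 15 tested members rose, 7 fell and 0 did not pass (8 and 7 adjusted over the list alone) at 9 Gy (list median 0.15, mean 0.0041, camera direction lower, adjusted p = 0.844). Among glycolysis and hypoxia genes, 9 of 27 tested members rose, 14 fell and 4 did not pass (9 and 14 adjusted over the list alone) at 9 Gy (list median -0.12, camera adjusted p = 0.126), and PDK1, which holds back pyruvate oxidation, had -1.14 ± 0.031 at 9 Gy and 0.62 ± 0.011 at 23 Gy, both from the deposited values. Among adhesion and cytoskeleton genes, 14 of 21 tested members rose, 6 fell and 1 did not pass (14 and 6 adjusted over the list alone) at 9 Gy (list median 0.24, camera adjusted p = 0.137), with ACTB at 1.01 ± 0.018. The 4 kept probes of ACTB ranged from 0.14 to 1.01. Among fibroblast and other stromal markers, 5 of 8 tested members rose, 2 fell and 1 did not pass (5 and 2 adjusted over the list alone) at 9 Gy (list median 0.11, camera adjusted p = 0.403), and among leukocyte markers 5 of 10 tested members rose, 1 fell and 4 did not pass (5 and 1 adjusted over the list alone) (list median 0.10, camera adjusted p = 0.237). From the deposited values at 9 Gy the medians of these 2 lists were 0.41 and 0.48, and neither was called (adjusted p = 0.579 and 0.231). Those of the basal and stem cell lists were 0.52 and 0.38 in the deposited values (adjusted p = 0.112 and 0.579). Under median centring, which moved the median of all genes to 0.28, directions of lists and genes at 9 Gy turned, and the BCL2 family (adjusted p = 0.0205), oestrogen response (0.0121), unfolded protein (0.0112) and adhesion (0.0239) lists were called higher. The unfolded protein list was also called without replicate 2 (0.0328) or 6 (0.0257).

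Between doses the median, mean and test of 4 lists that were not called differed in sign, namely DNA replication and G1/S, stem cell associated genes, adhesion and cytoskeleton, and stromal markers.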
